A study of Danio rerio with 30 samples.

How the data were processed

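Total RNA of single adult zebrafish brains was labelled with Cy3 and hybridised to Agilent zebrafish arrays, 4 to a slide, per the labels' protocols. The 30 scanner files hold spot intensity values made with Agilent Feature Extraction 10.1.1.1, which subtracted the background, detrended each array and set a floor on low signals, per the file headers. Their other columns, deposited beside the signals, are flags for outliers, saturation and spots well above background. Arrays of slides 5 to 8 were extracted from a pair of scanner gains and those of slides 1 to 4 from a single gain, per the file headers. Gain and scan session cannot be told apart.

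A deposited value table holds the authors' processed values, and its scale was found by setting each column against the scanner files. The table's 28 log2 columns and 2 log10 columns (control 3 and reactive 5) were made by the authors from the background-subtracted signal, with no centring between arrays, and spots at or below 0 have no value. Within a tolerance of 0.001, 21 of 30 columns equalled the file of their own sample, 8 columns (controls 1 to 8) equalled the file of the control 4 numbers away, and 1 (reactive 5) matched no file row by row, with sorted values within 0.00159 of log10 of its own file. The medians of the columns of controls 1 to 10 were 7.64, 7.87, 2.21 (log10), 7.17, 8.12, 8.19, 8.21, 7.71, 7.97 and 7.46. Those of proactive brains 1 to 10 were 7.87, 7.97, 7.69, 7.78, 6.70, 8.23, 7.98, 7.41, 7.38 and 7.25, and those of reactive brains 1 to 10 were 7.89, 7.44, 6.69, 6.36, 2.21 (log10), 7.53, 7.83, 7.43, 7.05 and 7.56. Scale and centring are thus known for all columns, the order of values in that of reactive 5 stays unknown, and a 1-colour value has no direction. The individual number of controls 1 to 8 stays unknown, which leaves their group as it is. As an alternative, the value table was used with each column at the file it matched, put on the log2 scale and scaled to its 75th percentile, without the column of reactive 5.

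Groups were taken from the labels, where a spelling of the reactive group in titles differs from its description. Control files 2 and 3 were the same array extracted separately, with the same median signal at 99.3% of spots and a correlation of 0.99992, where the other 434 pairs of arrays reached at most 2.62% and 0.973. Their mean was used as 1 sample. Slide 1 held proactive arrays 1 to 3, slide 2 controls 1 to 4, slide 3 reactive arrays 1 to 4, slide 4 controls 5 to 8, slide 5 proactive arrays 5 to 8 and slide 7 reactive arrays 5 to 8. Slide 6 held controls 9 and 10 and proactive arrays 9 and 10, and slide 8 proactive array 4 and reactive arrays 9 and 10. Scan session 1 held slides 1 to 4 and session 2 slides 5 to 8, with 8 and 2 control, 3 and 7 proactive and 4 and 6 reactive arrays. A planned rule that joined scan dates within 31 days put all arrays into 1 batch, so the model held no batch term. Sessions, split at a gap of 7 days, were tried as an alternative.

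For the main values, control spots and outlier flags were left out (2344 values or 0.292% of those tested), log2 of the processed signal was taken, the array's 75th percentile was subtracted and spots of a probe were averaged. The 75th percentile lay between 732 and 1880 in control, 604 and 1729 in proactive and 549 and 1437 in reactive arrays, and 52.4% to 80.6%, 59.1% to 77.1% and 63.2% to 82.9% of spots were well above background. Of 43603 probes on 43803 spots, 16127 were named through RefSeq accessions in a reference table of assembly GRCz12tu, without versions, giving 11313 symbols. Names were found for 15670 of 16798 accessions starting with NM, 7 of 7 with NR and 450 of 2659 with XM, 0 probes had several symbols, and 27476 probes stay unnamed here. Coordinates were not used here. For a gene with several probes the probe of highest mean was used, unnamed probes were kept singly, and a transcript was tested if well above background on at least 5 arrays of a group. This left 27685 transcripts, 10252 named and 17433 unnamed.

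Differences were tested with limma 3.58.1 in R 4.3.3, in 1 model of the 3 groups with slide as a random block (correlation 0.223), empirical Bayes moderation without a trend, and a Benjamini-Hochberg adjusted p under 0.05 within each comparison. All adjusted p-values of single genes are limma's. A modelled difference departs from the difference of group means where slides are weighted. A transcript not well above background on any array of a group has only a bound there. The bound sets the brighter group's mean against the mean over the dimmer group's arrays of the higher of 2 values, the array's lowest signal well above background and the probe's own. On simulated data with 200 changed genes among 27685, the test recovered 8.96%, 50.7% and 74.2% of genes changed by folds of 1.5, 2 and 4 for proactive minus reactive, with 7.29% of calls unchanged genes. The shares were 14.9%, 50.7% and 83.3% for proactive minus control, with 10.8% of calls unchanged genes, and 8.96%, 40.3% and 77.3% for reactive minus control, with 11.6%.

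Groups, tests, alternatives, 21 gene lists and 14 cell type lists were fixed before the data were examined. The gene lists were stress axis, serotonin, dopamine and noradrenaline, GABA, glutamate, immediate early genes, neuropeptides, synapse and vesicle, neurotrophin and growth factors, neurogenesis, clock, heat shock, oxidative phosphorylation, ribosomal proteins, proteasome, glycolysis, cholesterol synthesis, interferon response, acute inflammation, antioxidant defence, and gonadal steroid and thyroid signalling. The cell type lists were oligodendrocyte, radial glia, microglia, neutrophil, endothelium, erythrocyte, pituitary, photoreceptor, lens, skeletal muscle, skin, cartilage and bone, liver and gonad. Lists of at least 5 tested members were tested with limma's camera, with a preset correlation of 0.01 and with an estimated one, and with fry beside it, on values whitened with the slide correlation and adjusted over the lists of a comparison. The pituitary list, with 4 tested members, was described only.

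Genes are named by a rule. It takes the 10 largest named rises and falls past the threshold, or up to 5 of smallest p in a direction where fewer than 5 passed, up to 4 members of smallest p of a gene list or of a cell type list that differed, and the 5 of smallest p in the test of variability between proactive and reactive brains. Placeholder names give way to full symbols, except where they lead by fold. Some genes that the rule takes are not reported here. The probes A_15_P549462 and A_15_P107324 and single members of the oligodendrocyte, neutrophil, skeletal muscle and gonad lists were named after their values were seen.

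Variability per gene was tested with limma on absolute deviations from the group median, multiplied by the square root of n/(n - 1), with slide as a random block (correlation 0.0492). Variability per brain was the root mean square deviation from the mean of the other brains of its group, multiplied by the square root of m/(m + 1), where m is their number, and within slides 1 mean per slide and group was compared. An axis from reactive to proactive used the 200 transcripts of smallest p, chosen without the array placed. Missing values were filled with the gene's mean for the slide correlation, lists, principal components, variability and axis. Single values were compared by two-sided exact permutation tests where a group held under 10 brains, and otherwise by permutation tests with 100000 resamples, adjusted over 3 pairs. The similarity of the comparisons against controls was set beside 100 simulations without effects and beside split controls, and calls beside 100 splits of the samples and beside all splits that keep the arrays of a group on a slide together. The slide correlation was estimated on 3000 genes where single arrays were left out and on 500 for the splits. The tests of genes, lists, variability and axis were tested on simulated data. Tables were read and figures drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

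Alternatives were quantile normalization, normexp with an offset of 50 followed by the 75th percentile or quantile normalization, the authors' values, no filter or a strict filter on dim probes, slide as a fixed block or left out, the replicate number as a block, array weights, the mean of all probes of a gene, an intensity trend with robust moderation, only the groups compared, a fold minimum of 1.5, other axis sizes and each array left out. Since the files used here hold no mean spot signal, normexp was run on the median signal with the local background median, over probes without control spots. The individual numbers in the labels run over all groups, and whether they pair samples was checked by the correlation of deviations from the group means.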

Results

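Brains of adult zebrafish (Danio rerio) were profiled with 1-colour Agilent oligonucleotide arrays, each array holding Cy3-labelled RNA of a single brain. The 30 samples fell into 3 groups of 10, namely control brains, brains of proactive fish and brains of reactive fish. Coping style had been screened by boldness, as the time a fish took to leave a dark shelter for an open tank after a day without food. Fish that left early were taken as bold, here called proactive, and those that stayed inside as shy, here called reactive, while intermediate fish were discarded. The labels do not say how the control fish were handled, at what hour brains were taken, or the sex of the fish. The labels give each brain as a separate individual. The study asked how far gene expression differs between coping styles and between individuals of a style.

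Between 52.4% and 82.9% of spots were well above background on an array, and the number of arrays limits the precision of every value. Control arrays 2 and 3 held the same median signal at 99.3% of spots, against at most 2.62% for any other pair of arrays, and differed by less than the noise between arrays. They were counted as 1 sample, which left 9 control, 10 proactive and 10 reactive brains. Of 27685 genes and probes tested, 10252 carried a gene name. Signals are given as log2 values relative to the 75th percentile of the array, with the SD over brains, and differences between groups are log2 values from limma with their standard error (SE). Most slides held 1 group only, and slide was fitted as a random block. The first principal component held 11.8% of the variance, of which slide explained 95.9% and scan session 80.1%. The second held 9.65%, of which group explained 82.9% and slide 75.7%, with control brains apart from both screened groups.

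**Figure D1:**
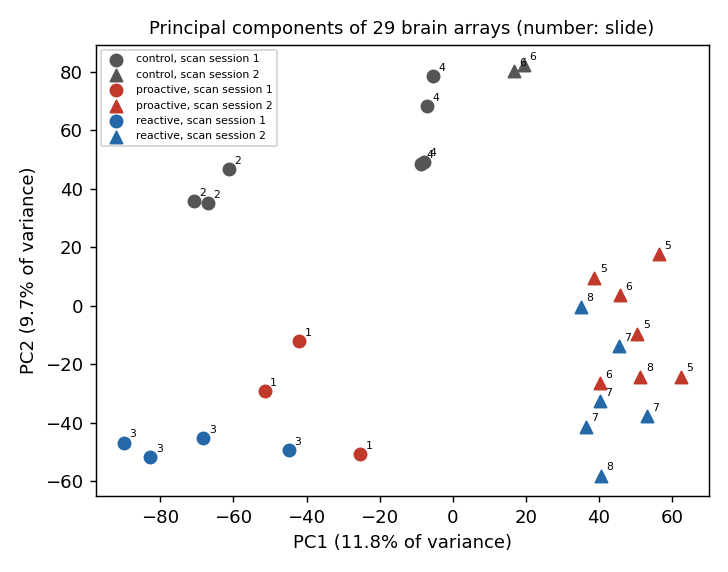
Principal components of the 29 separate brain arrays, with PC1 (11.8% of the variance) against PC2 (9.65%), colour for group, symbol for scan session and a number for the slide. Control arrays lie at the top and arrays of screened fish below them, while the sessions lie apart along PC1.

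The first comparison asked which transcripts separate bold from shy fish. The transcript zgc:165555, a gene of placeholder name, was lower in proactive than in reactive brains by a log2 difference of -3.07 (SE 0.47, adjusted p = 0.0105). Its signal was -3.43 ± 0.82 (SD, n = 10) in proactive and -0.49 ± 1.08 (SD, n = 10) in reactive brains, and -5.35 ± 0.85 (SD, n = 9) in controls, where it stood well above background on 7 of 9 arrays. Both screened groups exceeded the controls in this transcript, reactive brains by 5.10 (adjusted p = 2.34e-07) and proactive brains by 2.02 (adjusted p = 0.0154). The unnamed probe A_15_P549462 was lower in proactive brains by -3.06 (SE 0.53, adjusted p = 0.0384) and stood well above background on 2 of 10 proactive and 9 of 10 reactive arrays. These 2 were the only transcripts past the threshold, with 0 higher in proactive brains, and 1485 transcripts had an unadjusted p under 0.05.

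Among named genes with a small p that did not pass, ttll3, of the tubulin ligase-like family, had a log2 difference of -1.31 (adjusted p = 0.0721) and stood well above background on 5 of 10 proactive and 10 of 10 reactive arrays. The genes hhatlb (-2.78), with 2 of its 3 probes in that direction, and mkks (-0.66) were on the lower side too. The gene cyp8b1.1 was not well above background on any proactive array, and its mean in reactive brains was at least 1.12-fold higher. On the higher side stood hmgb3b (0.54), dnajb9b (0.98), nat10 (1.04), prune2 (0.85) and gyg1b (0.84), with adjusted p between 0.394 and 0.537.

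Of the lists fixed beforehand, 4 shifted between the coping styles by limma's camera test with a preset correlation, and 0 of the 4 calls held with an estimated correlation. Endothelial markers were lower in proactive brains, with 2 of 13 above 0, a median of -0.33 (-0.14 with normexp and the 75th percentile) and an adjusted p of 0.00134, against an adjusted p of 0.0565 with an estimated correlation. The tight junction gene cldn5b (-1.13) and the transcription factor gene fli1 (-0.58, with 2 of 4 probes in that direction) passed when adjusted over the list alone, where 2 of 13 markers did, while flt1 (-1.15) and kdrl (-0.85), receptors for vascular endothelial growth factor, did not, and stood well above background on 5 and 3 of 10 proactive arrays. Clock genes were higher in proactive brains, with 21 of 31 above 0 and an adjusted p of 0.00792 (0.0565 with an estimated correlation). The clock-controlled tefb (1.31) and bhlhe41 (0.95) passed when adjusted over the list alone, and the differences of bmal2 and cry2 were -0.88 and 0.83. Genes of cholesterol synthesis were above 0 in 17 of 20 cases, among them ebp (0.60), tm7sf2 (0.49), idi1 (0.71) and lss (0.49), with an adjusted p of 0.00134 (0.533 with an estimated correlation). Cytosolic ribosomal protein genes were above 0 in 11 of 77 cases, with rpl3 at -0.39 and rpl7, rpl30 and rps10 at -0.50, the direction of rpl30 turning to 0.13 after normexp with quantile normalization, and an adjusted p of 5.84e-05 (0.688 with an estimated correlation). After quantile normalization 34 of these 77 were above 0, with a median of -0.03. The bearing of saturated spots on this list was not tested. Over all genes tested 0 of the 858 members of all lists passed by limma, with 44 at an unadjusted p under 0.05.

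The call of zgc:165555 ended without reactive replicate 9 (adjusted p = 0.0568) or 10 (0.0633), that of A_15_P549462 ended without any 1 of 16 of the 29 arrays (adjusted p up to 0.225, without proactive replicate 4), and the count of transcripts was 11 without proactive replicate 9 and 16 without reactive replicate 1. With scan session in the model 14 transcripts passed, within session 1 alone 0 (949 at an unadjusted p under 0.05), and within session 2 alone 83. With slide as a fixed block the count was 106. There the difference comes from slide 8 alone, the only slide that held both groups, with 1 proactive and 2 reactive arrays. That count thus rests on 1 proactive brain.

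The second comparison set proactive against control brains. Proactive brains had less transcript of the period genes per1b (-2.37, SE 0.23, adjusted p = 8.44e-07) and per1a (-1.77, SE 0.22), repressors of the circadian clock, and of fkbp5 (-3.33, SE 0.57, adjusted p = 0.00107), a co-chaperone of the glucocorticoid receptor. The signal of per1b was 2.90 ± 0.30 (SD, n = 10) in proactive and 5.32 ± 0.66 (SD, n = 9) in control brains, and that of fkbp5 was -0.44 ± 1.39 (SD, n = 10) and 2.99 ± 0.81 (SD, n = 9). The immediate early gene nr4a1 fell by 2.50 on the log2 scale, and the transcription factor gene klf9, which responds to glucocorticoids, fell by 2.58. In all, 731 genes and probes passed the threshold, 267 higher and 464 lower, of which 159 and 155 were named.

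Large named falls were those of pcdh15b (-4.72), a protocadherin of hair cells and photoreceptors, hhatlb (-4.13), ugt1ab (-3.95), a glucuronosyltransferase, and fkbp5. The genes cacnb3a (-2.87), a calcium channel subunit, klf9 (-2.58), foxg1b (-2.58), a forkhead transcription factor, and the cytokine gene il26 (-2.58) fell as well. The largest named rises were those of stm (2.68, SE 0.73), which encodes an otolith matrix protein, shisa10.2 (2.50), the anion transporter slc22a7b.1 (2.37) and stoml3b (2.34). The tyrosine breakdown genes hgd (2.08) and hpdb (1.83), the ribosomal protein gene rpl31 (2.06), the homeobox gene lbx1a (1.95), zmat1 (1.86, SE 0.22) and lyplal1 (1.77) rose as well. Some of these differences rest in part on arrays where the gene was not well above background. It was well above on 3 of 10 proactive and 7 of 9 control arrays for ugt1ab, on 2 and 6 for il26, and on 8 of 10 proactive arrays for pcdh15b and klf9. Among control arrays it was so on 8 of 9 for shisa10.2, 7 for rpl31 and hpdb and 6 for stoml3b.

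Of 31 clock genes, 4 rose, 9 fell and 18 did not pass, and 7 rose and 13 fell when adjusted over the list alone. The repressor gene bhlhe41 fell by 1.62 and the cryptochrome gene cry3a rose by 1.25. The list was shifted down by camera (adjusted p = 0.0320), with an adjusted p of 0.288 with an estimated correlation. Of 40 immediate early and activity-dependent genes, per1a and per1b among them, 0 rose and 7 fell, including atf3 (-0.99) and nr4a1 (adjusted p of the list 5.44e-06, and 0.314 with an estimated correlation). When adjusted over the list alone, 1 of the 40 rose and 11 fell.

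Ribosomal protein genes were above 0 in 71 of 77 cases with a median of 0.30, and rpl31, rps26l (0.75, with 1 of 2 probes in that direction) and rps12 (0.78) rose while rps3 (0.63) did not pass. The list's adjusted p was 1.98e-09, and 0.436 with an estimated correlation, and after quantile normalization its median was 0.13. Of 76 nuclear-encoded genes of oxidative phosphorylation ndufa13 (0.57) rose, cox7a2l (0.47), atp5mc3b (0.53) and ndufaf1 (0.59) did not pass, and 65 were above 0 (adjusted p = 1.33e-05, and 0.436 with an estimated correlation). Among 46 genes of neurogenesis and proliferation the hairy-related transcription factor genes her6 (0.98) and her9 (0.91) and the cyclin gene ccnd1 (0.78) rose, and dlb (0.68) did not pass (adjusted p of the list 0.0320, and 0.436 with an estimated correlation).

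All 11 tested markers of radial glia and astroglia lay above 0, with aqp1a.1 at 0.62, ptgdsb.2 at 0.79, fabp7a at 0.62 and slc1a2b at 0.50, and 0 passed over all genes by limma, with 3 at an unadjusted p under 0.05 (adjusted p of the list 0.00987, and 0.288 with an estimated correlation). After quantile normalization 10 of the 11 lay above 0 and the median was 0.19 against 0.45, slc1a2b was at -0.036 after normexp with quantile normalization, and within scan session 1 alone ptgdsb.2 was at -0.16, fabp7a at -0.052 and slc1a2b at -0.36. Endothelial markers lay above 0 in 2 of 13 cases, with kdrl at -1.01 (well above background on 3 of 10 proactive and 5 of 9 control arrays), cldn5b at -0.80, tek at -0.46 and fli1 at -0.43, with 3 of its 4 probes in that direction (adjusted p = 0.0320, and 0.288 with an estimated correlation). Photoreceptor genes had a median of 2.22 (1.21 with normexp and the 75th percentile, 1.42 with normexp and quantile normalization) and 0 of 22 passed by limma, with 0 at an unadjusted p under 0.05, gngt1 at 3.84 (well above background on 8 of 10 proactive and 6 of 9 control arrays), crx at 2.74 (9 and 7), gnat2 at 2.08 and asmtl at 0.32 (adjusted p = 0.000436, and 0.667 with an estimated correlation).

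Single genes of other lists changed too. The glutamate receptor gene grin1b (-1.13, with 2 of 3 probes in that direction), the synaptic scaffold gene dlg1a (-1.29), the dopamine receptor gene drd4a (-0.97), the neuropeptide genes hcrt (-0.93), encoding hypocretin, and qrfp (-0.65), and the thyroid receptor gene thraa (-0.79) fell. The heat shock gene hsp70l (-1.47), the inflammation regulators nfkbiab (-0.96) and socs3a (-1.99) and the cholesterol synthesis gene hmgcrb (-0.65) fell as well, while mao (0.60), encoding monoamine oxidase, rose.

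With slide as a fixed block 32 transcripts passed, of which 28 were among the 731, within slide 6, the slide that held both groups, 0 (2819 at an unadjusted p under 0.05), and within scan session 1 alone 4, of which 0 were among the 731. Leaving out control replicate 9 gave 375, control replicate 10 433 and proactive replicate 9 443 transcripts. Of the 31 clock genes 2 passed by limma with slide as a fixed block, 8 without control replicate 9, 8 with normexp and the 75th percentile, 0 within session 1 alone (10 at an unadjusted p under 0.05), 0 within slide 6 alone (12 at an unadjusted p under 0.05), 7 within session 2 alone and 12 with the photoreceptor score of each brain in the model, where 647 transcripts passed. Without control replicate 9 the calls of stm, shisa10.2, slc22a7b.1, hgd, hpdb, klf9, il26, ccnd1, rps12, ndufa13, socs3a, hsp70l, hmgcrb, thraa, drd4a, mao, hcrt and qrfp ended, and without proactive replicate 10 that of lbx1a. The call of qrfp ended without any 1 of 17 of the 29 arrays, those of ccnd1 and hcrt without any 1 of 12, that of stm without any 1 of 11 and that of mao without any 1 of 8, with adjusted p up to 0.126. The processed values of the authors gave 67 higher and 304 lower, so that 18.1% of the calls were higher against 36.5%.

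**Figure D2:**
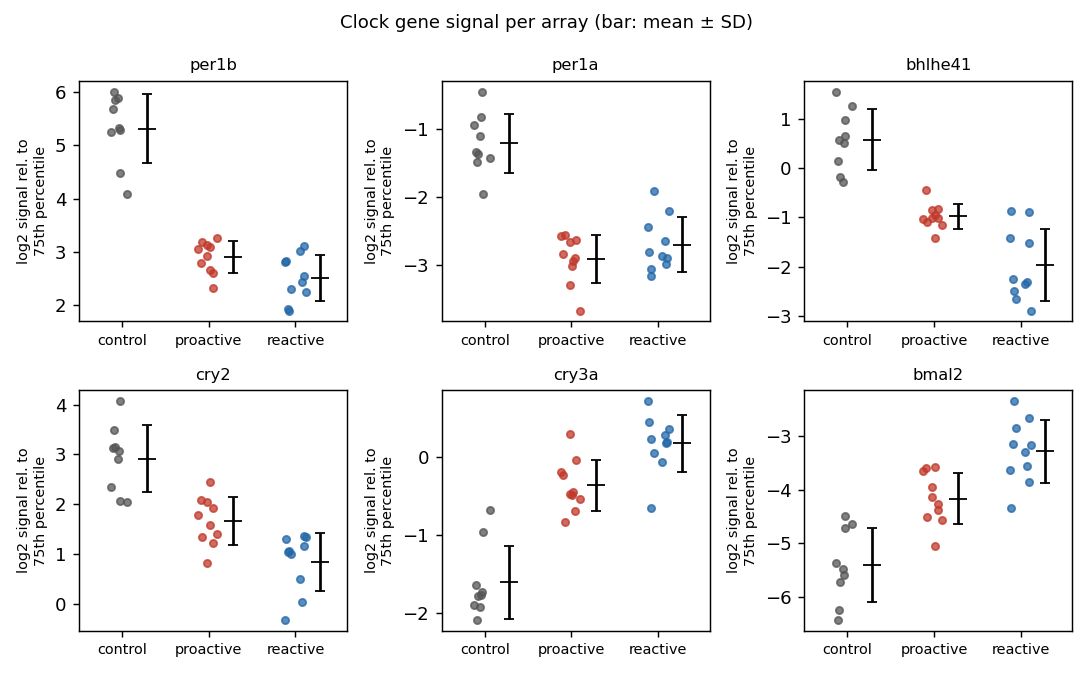
Log2 signal relative to the 75th percentile of the array for 6 clock genes in 9 control, 10 proactive and 10 reactive brains, with points for arrays and bars for the mean ± SD. The signal of per1b was 5.32 in controls, 2.90 in proactive and 2.51 in reactive brains, while cry3a and bmal2 lay higher in both screened groups than in controls.

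The third comparison set reactive against control brains. The clock genes per1b (-2.81, SE 0.25, adjusted p = 6.49e-08), bhlhe41 (-2.57, SE 0.30) and cry2 (-2.07, SE 0.31) fell in reactive brains, and bmal2 (2.13, SE 0.32), on the activating side of the clock, and cry3a (1.79, SE 0.23) rose. The signal of per1b was 2.51 ± 0.43 (SD, n = 10) in reactive and 5.32 ± 0.66 (SD, n = 9) in control brains. The glucocorticoid receptor co-chaperone gene fkbp5 fell by 2.89 on the log2 scale (SE 0.62, adjusted p = 0.00648). In all, 1083 genes and probes passed, 550 higher and 533 lower, of which 315 and 197 were named.

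The largest named rises were those of zmat1 (2.57, SE 0.24, adjusted p = 1.00e-07), shisa10.2 (2.47), pdha1b (2.47), of the pyruvate dehydrogenase complex, rpl31 (2.37) and ndrg1b. They were followed by bmal2, acot13 (2.12), an acyl-CoA thioesterase, mfap4.2 (2.11), the transglutaminase gene tgm1l4 (2.04) and lyplal1 (2.04). The caveolin gene cav3 was not well above background on any reactive array, where control brains were at least 4.57-fold higher (adjusted p = 0.0265). The cytokine gene il10 (-2.69), the carboxypeptidase gene cpa4 (-2.66), the egg coat gene zp3e (-2.62), asb4 (-2.62), rab34b (-2.59) and the phospholipase gene pla2g3 (-2.57) fell. Of these, cpa4 stood well above background on 1 of 10 reactive and 7 of 9 control arrays, il10 on 2 and 7, rab34b on 6 and 9 and pla2g3 on 8 and 8, and asb4 and the rising acot13 on 9 of 10 reactive arrays, so that the differences of cpa4 and il10 rest mostly on reactive values not well above background. On control arrays bmal2 stood well above background on 5 of 9, rpl31 on 7 and shisa10.2 on 8.

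Of 31 clock genes, 5 rose, 13 fell and 13 did not pass, and 7 rose and 16 fell when adjusted over the list alone. The list was shifted down by camera (adjusted p = 0.000196), and this was the single list call of the 7 that held with an estimated correlation (adjusted p = 0.00872). Of 40 immediate early genes 0 rose and 5 fell, among them per1b, per1a (-1.56), atf3 (-0.81) and nr4a1 (-2.06) (adjusted p of the list 0.000423, and 0.549 with an estimated correlation).

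Ribosomal protein genes were above 0 in 73 of 77 cases with a median of 0.53, and 10 rose, among them rpl31, rps26l (0.90), rps6 (0.72) and rps3 (0.81), with 32 when adjusted over the list alone. The list's adjusted p was 2.00e-16, and 0.478 with an estimated correlation, and after quantile normalization its median was 0.15. Saturated spots made up 1.35%, 0.543% and 0.193% of spots on slides 2, 4 and 6, which held controls. On slides 3, 7 and 8, which held reactive brains, they made up 0.624%, 0.195% and 0.152%. Whether saturation moved this list was not tested. The complex I genes ndufa13 (0.73) and ndufa3 (0.95) rose out of 76 genes of oxidative phosphorylation, with ndufaf1 (0.77) and atp5if1a (0.58) not past the threshold (adjusted p of the list 1.29e-05, and 0.549 with an estimated correlation). In this list 63 were above 0 with a median of 0.23, and after quantile normalization 46 with a median of 0.041. Of 46 genes of neurogenesis her6 (1.15), her9 (1.05), the proneural gene ascl1a (0.74) and the Notch ligand gene dlb (0.76) rose and 0 fell (adjusted p = 0.0158, and 0.549 with an estimated correlation).

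Radial glial markers lay above 0 in 8 of 11 cases, with fabp7a at 0.74, ptgdsb.2 at 0.71, slc1a2b at 0.67 and aqp1a.1 at 0.65, and 0 passed over all genes by limma, with 6 at an unadjusted p under 0.05 (adjusted p of the list 0.0333, and 0.478 with an estimated correlation). Their median was 0.61, and 0.24 after quantile normalization. Photoreceptor genes had a median of 3.09 (1.78 with normexp and the 75th percentile, 1.84 with normexp and quantile normalization) and 0 of 22 passed by limma, with 9 at an unadjusted p under 0.05, rcvrna at 4.79 (well above background on 8 of 10 reactive and 2 of 9 control arrays), rcvrn2 at 4.24 (8 and 4), gnat2 at 3.17 and asmtl at 0.59 (adjusted p = 1.29e-05, and 0.607 with an estimated correlation). Among other lists hcrt (-1.26), drd4a (-1.11), grin1b (with 2 of 3 probes in that direction), dlg1a (-1.22), sypa (-0.95), encoding synaptophysin, and igfbp1b (-1.79) fell. The complement gene c6.2 (-1.69), the sterol reductase gene tm7sf2 (-0.99) and hsf2 (-1.33), a heat shock transcription factor, fell as well, while the neuropeptide gene vip (0.74), the collagen chaperone gene serpinh1b (1.25), eno1b (0.80) of glycolysis and psmd4a (0.70) of the proteasome rose.

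With slide as a fixed block 86 transcripts passed, of which 13 were among the 1083, with 1 of 31 clock genes, and within scan session 1 alone 14 passed, with 2 of 31 clock genes, and within session 2 alone 1787. No slide held both groups. With slide fixed the difference was therefore linked only through the proactive arrays of slides 6 and 8, with 1 such array in slide 8. With the photoreceptor score of each brain in the model 708 passed, of which 653 were among the 1083, with 16 of 31 clock genes. Without control replicate 10 the calls of shisa10.2, ndrg1b, zp3e, ascl1a, dlb, ndufa3, eno1b, hsf2 and sypa ended, and without reactive replicate 10 that of igfbp1b. The call of dlb ended without any 1 of 20 of the 29 arrays, that of eno1b without any 1 of 14 and those of shisa10.2 and ndrg1b without any 1 of 13, with adjusted p up to 0.101.

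**Figure D3:**
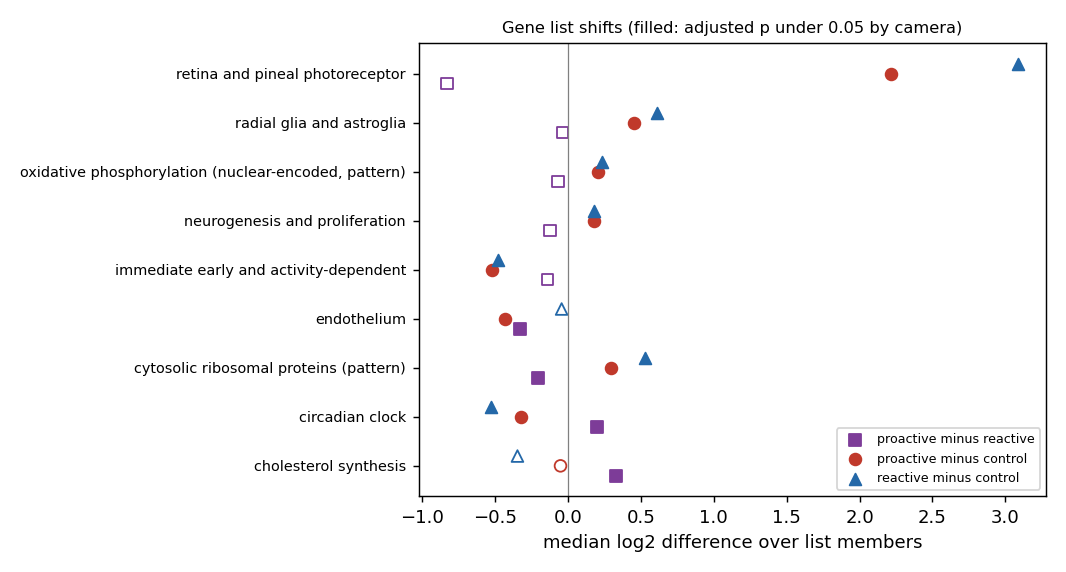
Median log2 difference over the members of each gene list shifted in at least 1 comparison, filled where limma's camera test with a preset correlation gave an adjusted p under 0.05. The median of the photoreceptor list was 2.22 for proactive minus control and 3.09 for reactive minus control, and that of immediate early genes -0.52 and -0.48.

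Photoreceptor genes, which a dissected brain can carry with pineal or retinal tissue, varied between brains within each group. Their mean log2 deviation over 22 genes was above 0 in 2 of 9 control, 5 of 10 proactive and 7 of 10 reactive brains, with medians of -2.40, -0.31 and 2.01. The difference between reactive and control brains was 2.71 (exact permutation p = 0.0192, adjusted p = 0.0576 over 3 comparisons, two-sided), and it did not pass.

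**Figure D4:**
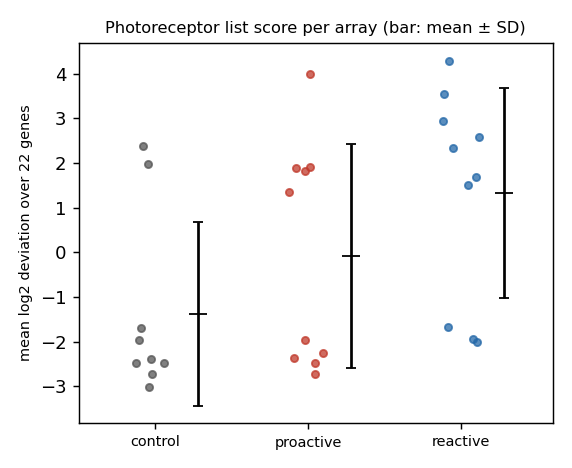
Mean log2 deviation of 22 photoreceptor genes in each of 9 control, 10 proactive and 10 reactive brains, with points for arrays and bars for the mean ± SD. Scores ran from -3.02 to 2.37 in control, -2.74 to 4.01 in proactive and -2.01 to 4.30 in reactive brains.

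The changes of both screened groups against controls were compared across all transcripts. Of the genes called in either comparison, 193 were higher and 246 lower in both, per1b, fkbp5, her6 and zmat1 among them, and 0 were called in opposite directions by limma. Independent lists, which leave out the shared controls, give 5.30 and 8.93. Simulations without effects that shared the controls gave 0 in either direction. Without effects an adjusted threshold leaves almost no calls, so this 0 is no test of shared changes. At an unadjusted p under 0.05, 1308 were higher and 1381 lower in both and 0 opposite, against 139.9, 136 and 0.18 in those simulations. Across transcripts, which are not independent replicates, the correlation was 0.731, against 0.528 in 100 simulations without effects that shared the controls. These simulations held a slide correlation but no scan session. Most control arrays were of session 1 and most screened ones of session 2, so session can move both comparisons the same way. The covariance was 0.275 against 0.107 simulated, a difference of 0.168, and 77.6% of transcripts had the same sign against 67.7% simulated. With the controls split by odd and even number the correlation was 0.474 and 0.485, and split by slide 0.188 and 0.284, where the covariance was 0.205 and 0.208 and, by slide, 0.105 and 0.149. Odd and even controls lay on the same slides, so the values split by number can still hold shared slide effects. No correlation without effects was simulated for either split.

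The study set out to measure variability between individuals of a group. The gene pou4f4, of the POU transcription factor family, had an SD of 0.64 in proactive, 0.28 in reactive and 0.14 in control brains, and slco2b1, an anion transporter gene, one of 0.37, 1.17 and 0.51. The gene dnase1 had SDs of 1.29, 2.48 and 1.18, si:dkeyp-106c3.2 of 1.05, 0.32 and 0.60 and si:ch73-299h12.4 of 1.23, 0.62 and 0.57. None of these 5 passed between proactive and reactive brains by limma (adjusted p = 1.00 each). The unnamed probe A_15_P107324, named after its values were seen, was the single transcript to pass, with an SD of 3.17 in proactive, 1.03 in reactive and 0.67 in control brains (adjusted p = 5.99e-06 against reactive brains by limma). Without any 1 of the proactive arrays 0 transcripts passed, and without control replicate 9 32 did. Over the 3 groups 1114 transcripts had an unadjusted p under 0.05. On data simulated with a spread 3 times as large in proactive brains this test found 1.5% of the changed genes.

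The mean deviation of a brain from its group over all genes was 0.821 ± 0.056 (SD, n = 9) in control, 0.836 ± 0.044 (SD, n = 10) in proactive and 0.848 ± 0.048 (SD, n = 10) in reactive brains, and no pair of groups differed (exact or permutation tests, adjusted p = 0.561 each, two-sided). Within slides, where 2 arrays of a group on 1 slide deviate equally by construction, 1 value per slide and group was taken. The mean was 0.705 ± 0.054 (SD, n = 3 slides) in control, 0.806 ± 0.035 (SD, n = 3) in proactive and 0.795 ± 0.045 (SD, n = 3) in reactive brains. No pair passed, with exact permutation p of 0.1 for proactive against control, the smallest that 3 against 3 allow, 0.2 for reactive against control and 0.7 between the styles.

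The position of the controls between the coping styles was measured along an axis of 200 genes from reactive (0) to proactive (1), with genes chosen without the array placed. Control brains stood at 0.520 ± 0.134 (SD, n = 9), proactive brains at 0.780 ± 0.211 (SD, n = 10) and reactive brains at 0.220 ± 0.184 (SD, n = 10). A data set simulated without group effects but with a slide correlation of 0.2 gave 0.566, 0.606 and 0.388, so that 0 is not the difference without effects for any pair. Proactive and reactive brains differed by 0.560, against 0.218 in that data set, proactive and control brains by 0.260 and reactive and control brains by -0.300. With genes chosen without any array of the same slide, proactive brains stood at 0.611 and reactive brains at 0.528, a difference of 0.0830. Controls were not placed anew and kept their 0.520, from genes chosen with all slides. The difference of reactive and control brains, 0.00846, thus sets positions from unlike genes side by side.

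**Figure D5:**
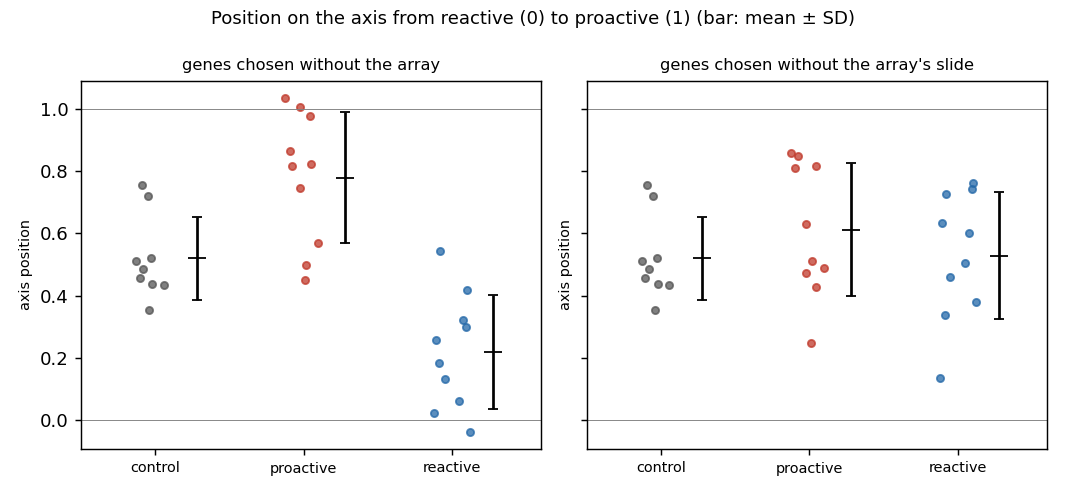
Position of each brain along the axis from reactive (0) to proactive (1), with genes chosen without the array at the left and without any array of its slide at the right, points for arrays and bars for the mean ± SD. Control points are the same on both sides, since only proactive and reactive brains were placed anew. Proactive and reactive means were 0.780 and 0.220 at the left, and 0.611 and 0.528 at the right.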

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

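The tests of slide, scan session, hour of sampling and type on clock genes, all tests on photoreceptor genes, the tests of slide and probe on the transcripts lower in proactive brains, and the splits by whole slides were chosen after the results were seen, while those of signal over background and of splits of single arrays were not.

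Clock genes differed between the controls and both screened groups. Slide as the cause was argued against for proactive brains by slide 6. There 12 of 12 genes called without that slide, adjusted over the list alone, kept their sign. Their median ratio was 0.999 (SE 0.106 over genes), and the ratio of their mean change was 1.02 (SE 0.0920). The latter SE, for 2 brains of each group in the slide, was taken from the spread of brains on the other slides. This test was widened from genes called over all genes, which were too few, after its first result was seen. Reactive brains share no slide with controls, and 1 of 31 clock genes passed there with slide as a fixed block. For them slide was argued against by 13 genes picked at an unadjusted p under 0.05 with proactive brains and control slide 2. The means of these genes differed between 3 reactive and 2 other control slides by 1.43, or 15.2 times the SE of 0.0942 over slides. That SE rests on these few slides. The pick included proactive arrays of slides 6 and 8, which also held controls and reactive brains measured here. Scan session was argued against by 18 of 18 genes called in reactive brains that stayed called with session in the model. For type alone, with controls a mixture of types, clock genes were picked likewise with 1 screened group and 1 part of the controls. Over 8 picks, which share genes and brains, 99.3% had the same sign in the other group against the other part. In each pick the mean signed difference was at least 8.71 times its SE over slides, which argues against type alone. Simulations without effects gave 64.6% with controls split by number and 49.7% by slide. They drew genes independently and over all transcripts, so they are no measure for clock genes that change together. A candidate explanation is another hour of sampling. In both comparisons 5 of 5 bmal and clock genes lay above 0 and 20 of the 26 other genes of the list below 0. The difference of medians was 1.45 (SE 0.525 over genes) in reactive and 1.18 (SE 0.378 over genes) in proactive brains. These SEs treat genes of the same brains as independent, and both comparisons share the controls. Of the 26, 3 rose in reactive and 2 in proactive brains, cry3a in both. Handling or feeding of the controls before sampling, which the labels do not give, stays open and untested.

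Photoreceptor genes were high in some brains and low in others in every group. Slide was argued against, since 22.6% of the within-group variance of the list score lay between slides, against a median of 26.7% for random slides. Retinal or pineal tissue carried with the brain may be the source, since the 22 genes had a median pairwise correlation of 0.752 within groups. The signal of gngt1, among the brightest, ran from -9.07 to 3.19 in control, -8.43 to 4.35 in proactive and -4.01 to 4.25 in reactive brains. Over all arrays the log2 range went from 1.25 for asmtl and 2.49 for aanat1 to 14.1 for opn1lw2. The pineal organ is itself part of the brain. Whether the groups differ cannot be told, since the smallest adjusted permutation p of 3 comparisons was 0.0576.

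Of the transcripts far lower in proactive than in reactive brains, 2 passed the threshold, zgc:165555 among them, and the rest did not. Slide stays open, since slide 8, which held both groups, had 1 proactive and 2 reactive arrays: 50 transcripts lower in proactive brains, chosen without it, had a median ratio of 0.708 (SE 0.140 over transcripts) within it, with 45 of 50 in the same direction, 50 chosen as higher had one of 0.280 (SE 0.129) with 34 of 50, and with genes chosen without the slide the difference along the axis was 0.0830 against 0.560. A sequence variant under single probes was argued against as the whole cause by the other probes of 36 genes, with a median ratio of 0.513 (SE 0.0876). Signal over background of the array could not be decided, with a within-group correlation of 0.214 over 29 arrays (permutation p = 0.266, Spearman's rho 0.152, permutation p = 0.429), and of 0.146 without the 2 arrays farthest from the median. Coping style itself stays open, with 2 transcripts past the threshold.

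Among 100 splits of the single arrays compared, the real one included, 4 called as many transcripts as the real 2 between proactive and reactive brains, with 8 as the highest other. That is just under the share of 0.05 set beforehand, and 100 splits cannot tell it from 0.05. A chance assignment of single arrays is thus not firmly excluded there. Without reactive replicate 9 or 10 the real count was 0 by limma. Between proactive and control brains 1 split, the real one, called as many (720, highest other 2), and between reactive and control brains also 1 (1053, highest other 14), so that a chance assignment of single arrays can be excluded. These real counts differ from 731 and 1083 because missing values were filled in and the slide correlation was estimated on 500 genes for the splits. For variability 32 splits called as many as the real 1, with 5 as the highest other, so that chance cannot be excluded. Most slides held 1 group, so splits of single arrays do not bear on slide. With the arrays of a group on a slide kept together there were 6, 13 and 6 splits, too few for a share under 0.05, with real counts of 2, 720 and 1053 and highest others of 150, 157 and 0. The split with 150 points to a structure of the samples beside coping style. It set 10 arrays of session 2 against 7 of session 1 and 3 of session 2, but another split of that balance called fewer than the real 2. Among the splits of proactive and reactive brains, session balance alone thus does not go with the count, and the cause stays open. The split with 157, of proactive and control brains, set 10 arrays of session 1 against 9 of session 2, so that calls there can go with scan session. Between proactive and reactive brains 14 transcripts passed with session in the model, 83 within session 2 and 0 by limma within session 1 (949 at an unadjusted p under 0.05).

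Single arrays lay far from the rest of their group in 31 of 375 groups of values tested, where chance sets apart about 1 in 20 groups, or 18.8. Control replicate 1 was highest for the score of cholesterol synthesis at 0.755 (next 0.192) and for acot13 at 0.63 (next -0.85). It was lowest for fkbp5 at 1.06 (next 2.48) and for foxg1b at -1.37 (next -0.19). Among other controls, ebp was lowest in replicate 2 at 0.64 (next 1.85), il10 in replicate 4 at -6.70 (next -5.16) and hmgcrb in replicate 8 at -1.04 (next -0.42), and dlg1a was highest in replicate 6 at 2.45 (next 1.88). In proactive brains, rps26l was highest in replicate 3 at 5.85 (next 5.42), and atp5if1a and hcrt in replicate 5 at 6.14 (next 5.62) and -1.82 (next -2.61). The signal of grin1b was lowest in proactive replicate 5 at -0.88 (next 0.21). In proactive replicate 6, cpa4 was highest at -3.33 (next -5.61) and eno1b lowest at 2.59 (next 3.44). In proactive replicate 9, ndrg1b was highest at 2.56 (next 0.55) and rab34b lowest at -7.11 (next -5.38). In reactive brains, fli1 and ugt1ab were lowest in replicate 1 at -0.15 (next 0.37) and -7.17 (next -4.05). In reactive replicate 3, dlg1a was highest at 1.84 (next 0.84), pla2g3 highest at -2.99 (next -4.20) and mao lowest at 3.63 (next 3.94). In reactive replicate 4, amh and eno1b were highest at -4.08 (next -6.41) and 4.71 (next 4.00), and hpdb was lowest at -4.37 (next -3.41). The signal of cimap1b was highest in reactive replicate 2 at -2.52 (next -3.66), that of ascl1a in reactive replicate 5 at 2.12 (next 1.71) and that of pdha1b in replicate 8 at 1.84 (next -0.63). In reactive replicate 9, dnajb9b was lowest at -4.79 (next -3.50), hmgb3b at 1.23 (next 1.65) and idi1 at -1.76 (next 0.23), and psmd4a was highest at 4.85 (next 4.56).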

How the results depend on the processing

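Settings with scan session, single slides, the photoreceptor score, controls split or left out by slide, genes chosen without the slide, variability with 1 value per slide and group, normexp on the median signal and the duplicate array counted separately were chosen after seeing the data. The planned settings of no slide block with batch kept, of slide without batch, of each batch alone and of batch not removed coincide with other settings, since there was 1 batch. Over all settings, 6692 values of named genes kept their direction and side of the threshold, 877 lost the threshold, 153 gained it and 5 reversed, and of the values of lists 158 kept it and 51 lost it. For the values below the cause was not tested, except that single sessions, slides and groups hold fewer arrays and that a slide as a fixed block leaves only slides with more than 1 group to inform a difference.

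Between proactive and reactive brains 2 transcripts passed. The count was 1 with quantile normalization, 1 with the authors' values, 1 without a filter, 1 with a strict filter, 27 with neither slide nor batch, 106 with slide fixed (from the 1 proactive and 2 reactive arrays of slide 8), 4 with array weights, 5 with the compared groups alone, 14 with session and slide, 49 with session and no slide, 0 in session 1 (949 at an unadjusted p under 0.05), 83 in session 2, 1 with the photoreceptor score and 7 without control slide 2. It ran from 0 to 16 with single arrays left out. Between proactive and control brains 731 passed. The count was 173 with normexp and the 75th percentile, 371 with the authors' values, 353 without a filter, 1922 with neither, 32 with slide fixed, 1305 with array weights, 2026 with session and no slide, 4 in session 1, 0 in slide 6 (2819 at an unadjusted p under 0.05) and 1312 without control slide 2. It ran from 375 to 873 with single arrays left out. Between reactive and control brains 1083 passed. The count was 379 with normexp and the 75th percentile, 430 with the authors' values, 474 without a filter, 3179 with neither, 86 with slide fixed, 482 with the compared groups alone, 2135 with session and slide, 4168 with session and no slide, 14 in session 1, 1787 in session 2 and 708 with the photoreceptor score, and ran from 817 to 1210 with single arrays left out. With the replicate number as a block the counts were 83, 2398 and 3496, in that order, without a slide block. Whether the numbers pair the samples could not be settled. Between proactive and reactive brains 5 of 10 pairs had a correlation over 0.1 (highest 0.231), and 4 arrays correlated best with their own number. Numbers also run with slide and scan session. Against controls 2 of 9 and 1 of 9 pairs exceeded 0.1, with 1 best match each, but the individual number of controls 1 to 8 is unknown.

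Of the lists, 4, 8 and 7 were called, in that order. With an estimated correlation 0, 0 and 1 were, with quantile normalization 11 and 5 in the comparisons of proactive brains, with normexp and the 75th percentile 9 between the styles, with normexp and quantile normalization 5 and with the authors' values 5 against controls, and with slide fixed 11 for reactive brains. The median of all genes moved to -0.13 for proactive minus reactive under the authors' values. Single genes reversed were rpl30 (proactive minus reactive, 0.13 with normexp and quantile normalization) and, for proactive minus control in session 1, ptgdsb.2 (-0.16), fabp7a (-0.052) and slc1a2b (-0.36), the last also with normexp and quantile normalization (-0.036). The correlation of both comparisons against controls was 0.479 with controls split by number and 0.236 by slide, and ran from 0.696 to 0.743 with single arrays left out. Transcripts differing in variability were 3 with quantile normalization, 0 with normexp and the 75th percentile (651 at an unadjusted p under 0.05), 0 with a strict filter (938) and 2 within slides, and ran from 0 to 32 with single arrays left out.

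Variability per brain for proactive minus reactive reversed to 0.0194 within slides, 0.0105 with 1 value per slide and group and 0.00931 with session removed. For proactive minus control it reversed to -0.0114 with quantile normalization, -0.169 with normexp and the 75th percentile, -0.0244 with the authors' values, -0.0366 without a filter, -0.0214 with a strict filter and -0.0145 with session removed, and passed within slides at 0.0896. For reactive minus control it reversed to -0.0104, -0.0421, -0.0149, -0.0115, -0.0153 and -0.0239 under the same settings, and passed within slides at 0.0702. These passes count 2 arrays of a group on 1 slide, which deviate equally by construction, as separate brains, and with 1 value per slide and group neither passed (adjusted exact p = 0.3 each). With single arrays left out these ran from -0.0205 to -0.00251, 0.00614 to 0.0295 and 0.0182 to 0.0415. The controls stood at 0.373 on an axis of 50 genes and at 0.656 on one of 1000. Differences along the axis were tested against 0. With genes chosen without the slide they were 0.0830 (proactive minus reactive), 0.0914 (proactive minus control) and 0.00846 (reactive minus control, reversed). Controls kept their main position there, so both differences from controls set positions from unlike genes side by side. Proactive minus control lost the threshold at 0.0194 with 1000 genes and 0.177 with quantile normalization, and reactive minus control at -0.225 with 50 genes. Arrays with 52.4% to 82.9% of spots well above background limit what can be said of dim transcripts.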

Other observations

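No test in this part was chosen after its result was seen, while the genes olig2, mpx, mylpfb, zp2.3, amh and cimap1b were named after their values were seen, as the few members of their lists past the threshold. The gene olig2, a transcription factor of the oligodendrocyte lineage, rose in proactive brains (0.82) and in reactive brains (0.78) against controls, and the other 8 of 9 tested oligodendrocyte genes did not pass. Of 28 skeletal muscle genes the fast myosin light chain gene mylpfb rose in both groups (1.02 and 1.27). Of 5 neutrophil genes mpx, encoding myeloperoxidase, fell in proactive brains (-1.37), and 0 passed by limma in reactive brains, with 1 at an unadjusted p under 0.05. Of 14 gonad genes the egg coat gene zp2.3 (-1.90) fell in proactive brains, and in reactive brains amh (-2.12), encoding anti-Müllerian hormone, fell and cimap1b (1.54), of cilia and sperm tails, rose. Of 29 acute inflammation genes 4 fell in proactive and 3 in reactive brains, and 0 rose, the cytokine gene il10 (-1.82) and the complement gene c6.2 (-1.14) among those of proactive brains and nfkbiab (-0.75) among those of reactive brains. That list did not shift by camera (adjusted p = 0.173 and 0.451), with 12 and 14 of 29 members above 0, nor did the other lists named so far. In proactive brains il10 stood well above background on 3 of 10 and zp2.3 on 5 of 10 arrays, in reactive brains amh on 1 of 10, and on control arrays il10 and amh on 7 of 9 and cimap1b on 5 of 9. Leaving out single arrays ended the call of nfkbiab in 21 of 29 cases, of c6.2 in 17 and of olig2 in 11 cases in reactive and 1 in proactive brains. It ended those of zp2.3 in 6, il10 in 4, mpx and amh in 3 and mylpfb in proactive brains in 2 cases, with adjusted p up to 0.110.

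Against controls, 2 of 19 stress axis genes fell in proactive and 1 in reactive brains, 2 of 33 neuropeptide genes fell in proactive brains, and 1 rose and 1 fell in reactive brains. Of 23 genes of dopamine and noradrenaline 1 rose and 1 fell in proactive brains and 1 fell in reactive brains, and of 11 serotonin genes 1 rose in proactive and 0 of 11, with 2 at an unadjusted p under 0.05, in reactive brains. In proactive brains 1 gene each fell of 21 glutamate, 43 synapse and vesicle, 43 heat shock, 18 gonadal steroid and thyroid and 20 cholesterol synthesis genes. In reactive brains 1 glutamate, 2 synapse, 1 cholesterol synthesis and 1 of 22 neurotrophin and growth factor genes fell, 1 of 30 glycolysis and 1 of 48 proteasome genes rose, and 1 heat shock gene rose and 1 fell. By limma 0 neurotrophin, glycolysis and proteasome genes passed in proactive brains (5, 3 and 2 at an unadjusted p under 0.05), and 0 gonadal steroid and thyroid genes in reactive brains (3). In the lists of GABA, interferon response, antioxidant defence, microglia, erythrocyte, pituitary, lens, skin, cartilage and bone, and liver 0 genes passed by limma in any comparison, where the antioxidant list had 1, 3 and 7 members at an unadjusted p under 0.05 (proactive minus reactive, proactive minus control and reactive minus control) and each of the others at most 3. The 13 endothelial markers, mostly below 0 in the comparisons of proactive brains, had a median of -0.04 for reactive minus control, with 1 at an unadjusted p under 0.05 and 0 past the threshold by limma. The 4 tested pituitary genes had medians of -0.17, -0.10 and 0.34 in that order of comparisons. Apart from the endothelial list in the comparisons of proactive brains, no list in this paragraph shifted by camera in the comparisons named.

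Adjusted over the list alone, proactive and reactive brains differed in 2 clock genes, 2 endothelial markers, 1 antioxidant gene, which was lower in proactive brains, and 2 neurotrophin and growth factor genes, 1 in each direction. Against controls, the counts adjusted over the list alone in proactive brains were 3 falls for stress axis, 2 rises and 3 falls for neuropeptides, 2 rises and 1 fall for dopamine and noradrenaline, 2 rises for serotonin, 1 rise and 2 falls for gonadal steroid and thyroid, and 2 rises and 6 falls for gonad genes. In reactive brains, adjusted over the list alone, 1 acute inflammation gene rose and 4 fell, 3 heat shock genes rose and 2 fell, 2 dopamine and noradrenaline genes rose and 3 fell, 2 gonad genes rose and 3 fell, 2 each of the serotonin, liver and skeletal muscle genes rose, and 2 each of the glutamate, stress axis and cholesterol synthesis genes fell. The median, the mean and the direction of the test differed in sign for stress axis (0.12 and -0.23, down) and glutamate (0.07 and -0.05, down) in proactive minus control, for cholesterol synthesis (-0.05 and 0.07, up) and for dopamine and noradrenaline (-0.01 and 0.13, up). For reactive minus control they differed in sign for stress axis (0.04 and -0.20, down), neurotrophin (0.13 and -0.09, up), gonad (0.06 and -0.28, down), oligodendrocyte (-0.13 and 0.01, up), neutrophil (0.25 and 0.02, down), endothelium (-0.04 and 0.02, up), glycolysis (-0.01 and 0.02, up), proteasome (-0.01 and 0.04, down) and skeletal muscle (-0.07 and -0.06, up). For proactive minus reactive they differed for GABA (-0.02 and -0.05, up), erythrocyte (-0.10 and -0.15, up), stress axis (-0.04 and -0.03, up), dopamine and noradrenaline, gonadal steroid and thyroid, and radial glia, the last 3 with medians of 0.07, -0.01 and -0.04, and each tested up.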
